A study of Arabidopsis thaliana with 8 samples.

How the data were processed

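Cotyledons of 2-week-old Arabidopsis thaliana seedlings of the Col-0 ecotype were profiled on one-colour Affymetrix arrays in 4 genotypes: the wild type, a knockout of NUDX6 (KO-nudx6), a knockout of NUDX7 (KO-nudx7), and the double mutant that lacks both. Each genotype had 2 arrays, 8 in all, which the labels call biological replicates and number 1 and 2 in every genotype. Per the labels' protocols, total RNA was copied to cDNA and transcribed in vitro with biotin-labelled nucleotides.

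The deposited values are linear signal intensities, 1 per probe set and array, made with GCOS per the submitters' processing notes. The version and settings of GCOS, any background step and any detection calls are not given in the sources used here. After the highest and lowest 2% of values were set aside, the mean deposited intensity lay between 500.0 and 500.1 on every array, so the arrays had been scaled to a common level before deposit. Array medians lay between 160.6 and 180.9. The number of arrays limits the precision, and signals near the bottom of the scale carry more error than bright ones.

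The table held 22810 probe sets, of which 64 were control probe sets and were left out of the tests. Of the other 22746, the platform annotation used here paired 13513 with 1 gene and 503 with several, and listed no gene for 8730. Symbols were updated through the gene table of the TAIR10.1 assembly, where 13436 of the single-gene probe sets were matched at 13286 loci. Probe sets with several genes or none are given by their ID. No assembly is named by the authors, so no coordinates are given.

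A pseudocount of 5, the 10th percentile of all values, was added before taking log2, and log2 fold changes are on that log2(signal + 5) scale, which understates the change of dim probe sets. Probe sets below the 40th percentile of the mean log2 value, a mean signal of about 89.0, were left out, which kept 13648 probe sets. A model with a mean per genotype was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend, 4 residual and 3.4 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of adjusted p 0.05. The 7 comparisons were each mutant against wild type, the mutants against one another, and the interaction, which is the double mutant minus both single mutants plus wild type. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading, for describing the arrays and for plots. The simulations were run in R.

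The replicate numbers marked a difference in array processing. The median of the poly-A spike-in probe sets was 2.2 to 4.2 on the replicate 1 arrays and 132.7 to 178.4 on the replicate 2 arrays, and that of the BioB hybridisation controls was 32.7 to 49.1 and 378.1 to 428.2. Deviations from the genotype means correlated at 0.35 to 0.70 across probe sets in the 6 pairs of genotypes, and arrays of one number had a median correlation of 0.9734 with each other against 0.9524 for arrays of one genotype. The numbers were therefore taken to pair the arrays. The labels call them biological replicates, so the plants may also differ between the numbers. Such a difference in transcripts cannot be told apart from one of processing. The fit without the replicate number is the one chosen first, and the fit with the number as a fixed term (3 residual and 5.9 prior degrees of freedom) is called the blocked fit. Each number holds 1 array per genotype, so values within a number have no spread of their own. Both fits pool the spread over the genotypes. Deviations of the double mutant correlated at 0.35 to 0.50 with those of the other genotypes, which correlated at 0.63 to 0.70 among themselves. The pooled spread of the blocked fit may therefore be too large for the single mutants and too small for the double mutant.

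Named genes followed a rule. For each comparison against wild type these were the 10 largest log2 fold changes in each direction among probe sets past the threshold that stand for 1 named gene and whose mutant signals both lay on one side of both wild-type signals. For the other comparisons the rule took 5 in each direction, and where none passed, the 5 with the smallest p, given as values. It also took up to 4 members per gene list and comparison, those past the threshold first, and NUDX6 and NUDX7 always. The rule was applied to the fit without the block and again to the blocked fit, the second of these after seeing the data. Any other probe set was chosen after its values were seen.

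Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A gene's brightest probe set stood for it. The samples, tests, alternatives, named-gene rule and 21 gene lists with 387 members were fixed before the data were examined. Only 56 of those members had a probe set listed for them, and 2 lists reached the 5 tested members needed for a set test. A further 16 lists with 378 members were therefore compiled from the genes listed in the annotation, after seeing the data, and were adjusted apart from the fixed lists. Some of their members are listed by locus alone. Tests of these added lists describe the data at hand and are not independent support. Members of smaller lists are given as values.

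Alternatives fixed in advance were a pseudocount of 20, a floor in place of the pseudocount, no filter, a 60th percentile filter, quantile normalization, scaling to the 75th percentile, eBayes without a trend or robust, a 2-fold limit, the replicate block, only the 4 arrays of the 2 groups compared, and leaving out each array in turn. The list tests with 1 array left out used the fit without the block. Leaving out an array of a compared genotype then sets unequal replicate numbers against each other. These list values therefore also carry the difference between the numbers. After seeing the data the same alternatives were run on the blocked fit. The models were tested on simulated data: in 20 runs with 13648 probe sets for the double mutant against wild type, the fit without the block recovered on average 4.5 of 100 probe sets changed 2-fold and 74.5 of 100 changed 4-fold with 0.05 false calls, and the blocked fit recovered 80.0 and 99.9 with 14.75 false calls. In 100 simulations of an unchanged double mutant that shared the wild-type arrays, the blocked fit gave at most 5 false calls. Both sets of simulations drew the noise of each probe set independently, with the same spread in every genotype. In the data probe sets vary together, with an estimated correlation of 0.554 in the immune list in the blocked fit. The simulations therefore do not show how many of the blocked calls are false.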

Results

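Transcript levels were measured in cotyledons of seedlings without NUDX6 (KO-nudx6), without NUDX7 (KO-nudx7), without both (the double mutant) and of the wild type, 2 arrays for each genotype. The series addresses what the loss of 1 or both of NUDX6 and NUDX7, Nudix hydrolases that cleave ADP-ribose and NADH, does to gene expression in a photosynthetic organ. The first principal component held 46.8% of the variance over the 13648 tested probe sets and ordered the arrays of each genotype by replicate number. The second component held 26.3% and placed both double-mutant arrays apart from the rest, at -23.6 and -31.8, while the other 6 arrays lay between -7.5 and 23.4.

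**Figure D1:**
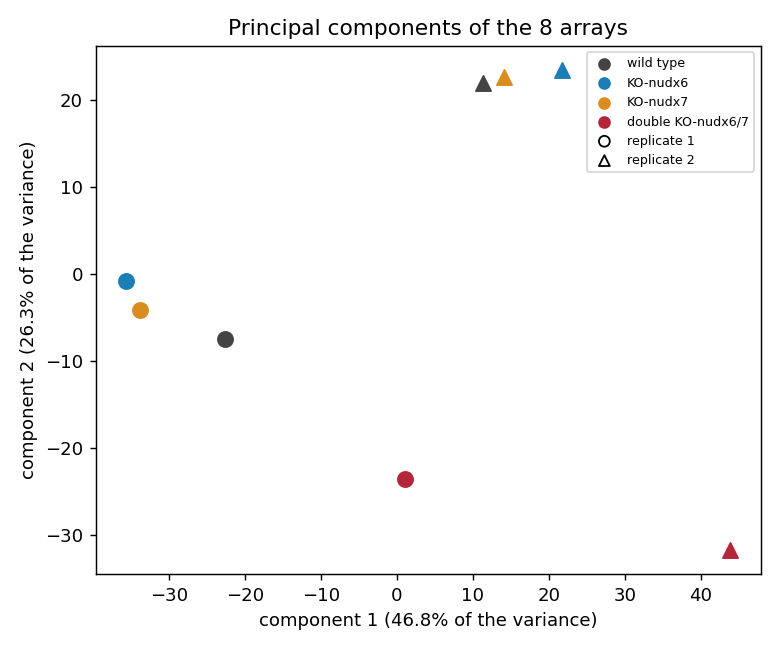
Scores of the 8 arrays on the first 2 principal components (axes in units of log2 signal, with the percent of variance), 1 point per array. The double-mutant arrays sit lowest on the second component, at -23.6 and -31.8, and the first component separates replicate 1 from replicate 2 within each genotype.

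NUDX6 (AT2G04450) and NUDX7 (AT4G12720) were paired with no probe set in the annotation used here, so the knockout labels were not checked on the targeted genes. A pair of probe sets for which the annotation lists no gene, chosen after their values were seen, followed the genotypes. The annotation does not settle whether either of them measures NUDX6 or NUDX7, so any call of these probe sets may be of a targeted gene itself. The signal of 263852_at was 448 and 429 in wild type and 481 and 407 in KO-nudx7, but 103 and 120 in KO-nudx6 and 69 and 86 in the double mutant. The signal of 254784_at was 2357 and 2379 in wild type and 1933 and 4780 in KO-nudx6, but 180 and 174 in KO-nudx7 and 225 and 201 in the double mutant.

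In KO-nudx6, against wild type, the transcript of AT1G26920 rose from a signal of 46 ± 8 (SD, n = 2) to 1006 ± 134 (SD, n = 2). This is a difference of 4.32 on the log2 scale (SE 0.21, limma adjusted p = 0.0012), and both KO-nudx6 arrays lay above both wild-type arrays. The wild-type signals lay below 89.0, the mean signal of the filter on dim probe sets, and signal over background was not analysed. The sizes of the differences of AT1G26920 from wild type and of its interaction are uncertain. AT1G26920 was the 1 probe set of 13648 past the threshold. At an unadjusted p under 0.05 there were 85, where exact p-values would give 682 by chance in any comparison with no change. The fit without the block counts the difference between replicate numbers as spread, so fewer than 682 are expected from it. That is not the whole reason, as the blocked fit also stayed below 682 in KO-nudx6 (311) and KO-nudx7 (539). Wherever 682 is given below, it is this nominal number and not a measured baseline. The blocked fit, with 311 at an unadjusted p under 0.05, called 2, the second being 263852_at, which fell by 1.93 on the log2 scale (adjusted p = 0.041 blocked and 0.16 without the block). With the 4 arrays of these genotypes alone the count was 0, as the adjusted p of AT1G26920 became 0.053. Of the 45 tested members of the fixed lists, limma called 0 in KO-nudx6 over all genes tested and 0 adjusted over the list alone, with and without the block. The largest values among them belonged to WRKY53 (0.65, SE 1.47), SAG29, a senescence-associated sugar transporter (-0.53, SE 0.99), AT2G25625 (-0.53, SE 0.63), and DFR of anthocyanin synthesis (-0.49, SE 0.31), each with an adjusted p of 1.

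The 7 nuclear photosynthesis genes had a median log2 difference of -0.08 in KO-nudx6 (adjusted p = 0.20, but 0.0095 without KO-nudx6 replicate 1) and the 5 genes of reactive oxygen species scavenging one of 0.04 (adjusted p = 0.30). Among the lists compiled later, the 15 cell division and histone genes were higher as a set in KO-nudx6, with a median of 0.17 and 13 of 15 above 0 (camera adjusted p = 0.010). Singly 0 of the 15 passed in limma, over all genes tested or over the list alone, in either fit. KINESIN-12B stood at 0.32, BUB3.2 at 0.31 and the centromeric histone HTR12 at 0.26. The set did not pass with an estimated correlation (adjusted p = 0.99 with an estimated correlation). Its median was 0.02 in replicate 1 and 0.24 in replicate 2. Its median was 0.29 without wild type replicate 1, 0.07 without wild type replicate 2 and 0.11 without KO-nudx6 replicate 1. The adjusted p became 0.66 without wild type replicate 2 and 0.15 without KO-nudx6 replicate 2, 0.19 without the filter and 0.27 with the stricter filter.

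In KO-nudx7, the same transcript of AT1G26920 rose to a signal of 1217 ± 157 (SD, n = 2), a difference from wild type of 4.6 on the log2 scale (SE 0.21, adjusted p = 0.00079). It was again the 1 probe set past the threshold in limma, with 150 at an unadjusted p under 0.05 against 682 by chance. The blocked fit, with 539 at an unadjusted p under 0.05, called 2, adding 254784_at, which fell by 3.71 on the log2 scale (adjusted p = 0.0076 blocked and 0.10 without the block). The count was also 2 without KO-nudx6 replicate 1, without KO-nudx6 replicate 2, and with the 4 arrays of these genotypes alone. Among the fixed lists, SAG29 (-1.89, SE 0.99), DFR (-1.45, SE 0.31), STZ (-0.90, SE 1.9), COR15A (-0.77, SE 0.45) and the stromal ascorbate peroxidase SAPX (-0.72, SE 0.77) had the largest values and did not pass over all genes tested (adjusted p = 1 for each). Of the 45 members of the fixed lists, 1 passed adjusted over the list alone without the block, which was DFR (adjusted p = 0.0039 over 2 genes), and 2 with the block, DFR and SAPX (adjusted p = 0.041 over 5 genes).

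The nuclear photosynthesis genes had a median of -0.09 in KO-nudx7 (adjusted p = 0.53). The reactive oxygen species genes had a median of 0.01 and a mean of -0.20, which differ in sign, and a camera direction of up (adjusted p = 0.53). Of the lists compiled later, the 10 genes of ATG8 and related autophagy proteins were higher as a set, with a median of 0.16 (adjusted p = 0.0011, but adjusted p = 0.77 with an estimated correlation). ATG8E stood at 0.55 (SE 0.21), ATG3 at 0.35 (SE 0.16) and ATG8C at 0.34 (SE 0.18), each with a blocked adjusted p of 0.99. The median was 0.38 in replicate 1 and 0.04 in replicate 2, and 0 of the 10 passed singly in limma in either fit. The median of the set was 0.06 without wild type replicate 1 (adjusted p = 0.39), 0.10 without KO-nudx7 replicate 1 (0.27), and 0.29 without wild type replicate 2 and without KO-nudx7 replicate 2.

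**Figure D2:**
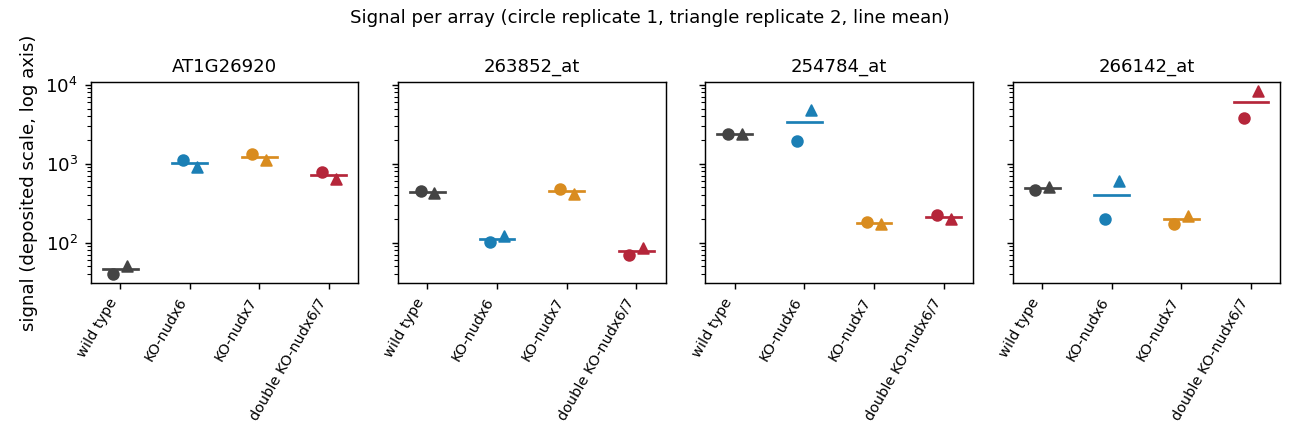
Signal per array (log axis) of AT1G26920 and of selected probe sets in the 4 genotypes, with a circle for replicate 1, a triangle for replicate 2 and a line at the mean. AT1G26920 lies at 40 and 51 in wild type and between 634 and 1328 on the 6 mutant arrays.

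In the double mutant, against wild type, the named genes that rose most in the blocked fit, beside AT1G26920, included peroxidase, osmotin-like, glucanase and defensin genes. The class III peroxidase genes Prx37 and PRX52 rose by 3.19 (blocked SE 0.32, adjusted p = 0.0059) and 2.33 (adjusted p = 0.016) on the log2 scale. The osmotin-like gene OSM34 rose by 3.1 (adjusted p = 0.0059), the glucanase-family gene AT4G16260 by 2.69 (adjusted p = 0.013), and the jacalin-lectin gene JAL23 by 2.25 (adjusted p = 0.034). The plant defensin genes PDF1.2 and PDF1.2b rose by 2.06 and 1.85 (adjusted p = 0.021 and 0.023), the methionine sulfoxide reductase gene MSRB9 by 1.92 (adjusted p = 0.026), and AT1G76470 and AT5G22530 by 2.35 and 1.95. AT1G26920 rose to 710 ± 108 (SD, n = 2), by 3.82 on the log2 scale (SE 0.21, adjusted p = 0.0031 without the block). The genes named before AT1G26920 passed in the blocked fit and not without the block, where the adjusted p of Prx37 was 0.41. OSM34 stood at 2.25 in replicate 1 and 3.95 in replicate 2, Prx37 at 2.64 and 3.73, PRX52 at 2.44 and 2.22, and PDF1.2 at 2.42 and 1.69. JAL23 stood at 1.44 and 3.05 and AT1G76470 at 1.56 and 3.14, and without wild type replicate 2 the value of JAL23 was 1.42 (adjusted p = 0.27).

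Among the transcripts that fell in the double mutant in the blocked fit were those of the subtilase genes AT2G39850 (-2.19, adjusted p = 0.0059) and AT5G59130 (-2.19, adjusted p = 0.013), and of the glutaredoxin-family gene AT2G47880 (-2.26, adjusted p = 0.015). AT3G46490 fell by 2.36 (adjusted p = 0.006), the Rab-acceptor gene PRA1.F1 by 1.89 (adjusted p = 0.015), and GIS, a zinc-finger regulator of trichome initiation, by 1.5 (adjusted p = 0.029). The other named genes that fell were AT1G69523 (-1.57), AT1G67870 (-1.55), AT1G70420 (-1.54) and AT5G01790 (-1.49). AT3G46490 stood at -2.01 and -2.71 in the 2 replicate numbers, AT2G39850 at -1.90 and -2.49, AT1G69523 at -1.04 and -2.09 and AT1G70420 at -0.92 and -2.17. Without wild type replicate 2 the value of AT1G69523 was -1.01 (adjusted p = 0.30). Mean signals lay below 89.0 in wild type for AT5G22530 and in the double mutant for AT3G46490, AT5G59130, GIS and AT5G01790. The sizes of these differences are uncertain too.

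**Figure D3:**
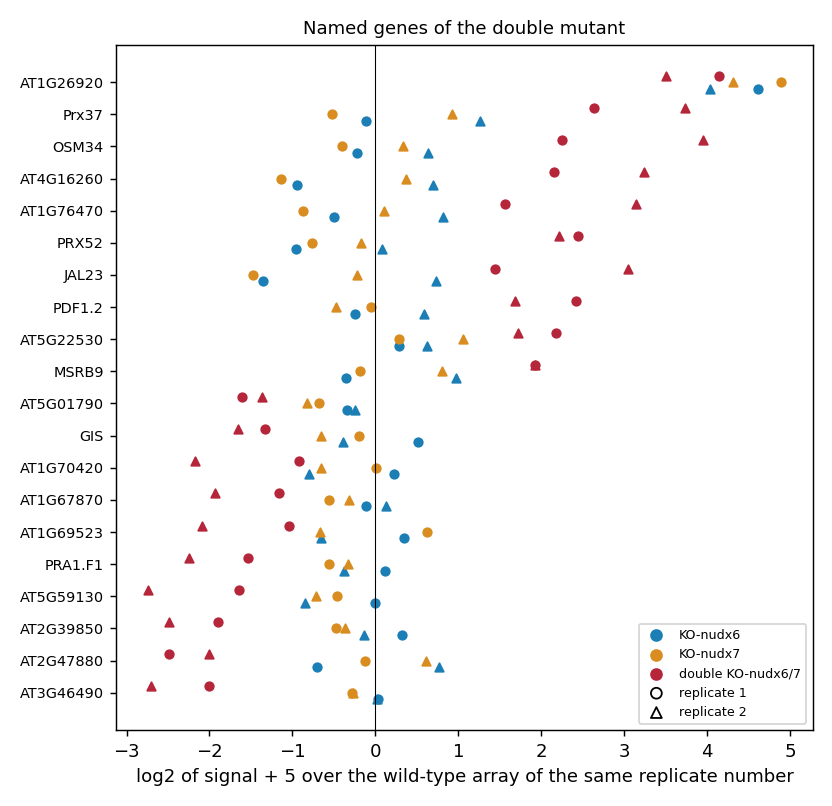
Log2 difference of each mutant array from the wild-type array of the same replicate number for the named genes of the double mutant, with a circle for replicate 1 and a triangle for replicate 2. The double-mutant points of OSM34 lie at 2.25 and 3.95 and its single-mutant points between -0.40 and 0.64.

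Without the block limma called 2 probe sets in the double mutant, AT1G26920 higher and 263852_at lower, with 1213 at an unadjusted p under 0.05 against 682 by chance. The blocked fit called 347, 168 higher and 179 lower, with 2717 at an unadjusted p under 0.05, and 152 of the 347 stand for a named gene. Its spread is pooled over the genotypes and may be too small for the double mutant, so these p-values may be too low. The called probe sets had a median log2 difference of 1.2 (higher) and -1.01 (lower) in the double mutant, against -0.02 and -0.06 in KO-nudx6 and 0.00 and -0.14 in KO-nudx7. The differences of the double mutant correlated at 0.44 across probe sets between the replicate numbers (probe sets are not independent), against -0.10 for KO-nudx6 and 0.09 for KO-nudx7. The blocked count depended on single arrays: it was 123 without wild type replicate 1, 2 without wild type replicate 2, 167 and 146 without KO-nudx6 replicate 1 and 2, 8 without KO-nudx7 replicate 1, 8 without KO-nudx7 replicate 2, 972 without double KO-nudx6/7 replicate 1 and 155 without double KO-nudx6/7 replicate 2. Without the block the count was 0 without double KO-nudx6/7 replicate 1, where AT1G26920 had an adjusted p of 0.065, and 1 when wild type replicate 2, KO-nudx7 replicate 1, KO-nudx7 replicate 2 or double KO-nudx6/7 replicate 2 was left out. Of the 8 leave-one-out blocked fits, AT1G26920 passed in 8, AT2G39850 in 7, OSM34, Prx37, PRX52, AT4G16260, AT1G76470, AT3G46490, AT5G59130 and PRA1.F1 in 5, PDF1.2, JAL23, MSRB9, AT2G47880, AT1G67870 and AT5G01790 in 4, GIS in 3, and AT1G69523 and AT1G70420 in 2.

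The 7 tested nuclear genes of the photosynthetic apparatus were lower in the double mutant than in wild type. The fixed list had 40 members, of which only these 7 had a listed probe set, so the others were not tested. All 7 tested members of the fixed list lay below 0, with a median of -0.55 (camera adjusted p = 2.4e-05, but adjusted p = 0.20 with an estimated correlation). PSAN, a subunit of photosystem I, fell by 0.79 (blocked SE 0.12, adjusted p = 0.021) and LHCB4.2, a light-harvesting protein of photosystem II, by 0.76 (blocked SE 0.12, adjusted p = 0.024). These were the 2 of 7 past the threshold over all genes tested in the blocked fit, and 4 of 7 passed adjusted over the list alone; without the block these counts were 0 and 2. PSBY (-0.56), LHCB4.1 (-0.55), PSAE-1 (-0.33), PSBW (-0.31) and RCA (-0.23) did not pass over all genes tested. Random lists of probe sets with a similar signal had a median of -0.24 in the same comparison, so part of this shift was shared by other bright probe sets. The list median was -0.41 in replicate 1 and -0.61 in replicate 2, and it was -0.40 after quantile normalization and -0.58 with 75th percentile scaling. Its median under leave-one-out ranged from -0.72 to -0.27, the latter without double KO-nudx6/7 replicate 2, and PSAN and LHCB4.2 each passed in 3 of the 8 leave-one-out blocked fits.

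Plastid-encoded transcripts and a wider list of thylakoid genes were lower as well, in lists compiled later. The thylakoid list repeats members of the fixed photosynthesis list, among them PSAN and LHCB4.2, so it is not separate support. Of 68 plastid-encoded genes 65 lay below 0, with a median of -0.45 (adjusted p = 9e-14, but adjusted p = 0.45 with an estimated correlation). Among them psaJ fell by 1.38 (blocked adjusted p = 0.016), psbA, which encodes the D1 protein of photosystem II, by 1.0 (adjusted p = 0.033) and atpF by 0.98 (adjusted p = 0.031). These 3 passed over all genes tested in the blocked fit and 33 passed adjusted over the list alone, and without the block both counts were 0. The signal of psbA was 7462 and 4472 in wild type and 3077 and 2722 in the double mutant. It was also low in KO-nudx7, at 3658 and 2170, and stood at 5635 and 3051 in KO-nudx6. The lower psbA was therefore not particular to the double mutant. The 39 genes of thylakoid, Calvin cycle and chlorophyll synthesis had a median of -0.44 (adjusted p = 4.6e-10, but adjusted p = 0.53 with an estimated correlation), with NdhL at -0.91 (blocked adjusted p = 0.037) beside PSAN and LHCB4.2. The thylakoid median was -0.29 without wild type replicate 1, -0.75 without double KO-nudx6/7 replicate 1 and -0.15 without double KO-nudx6/7 replicate 2. These fits had no block and set unequal replicate numbers against each other, so the difference between the numbers enters the values. The medians were -0.37 and -0.55 for the plastid list and -0.23 and -0.60 for the thylakoid list in replicate 1 and 2. The 3'/5' signal ratio of GAPDH, a sign of RNA quality, was lowest on the double-mutant arrays in both replicate numbers (2.49 and 1.93), while those of actin (5.85 and 2.95) and ubiquitin (3.69 and 2.88) were highest in replicate 1 and lowest in replicate 2. In the blocked fit psaJ passed in 4, atpF in 3, psbA in 2 and NdhL in 1 of the 8 leave-one-out fits.

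The 35 immune and salicylic acid responsive loci, a list compiled later, were higher as a set in the double mutant against wild type, with most members not past the threshold singly. This list was compiled after the data were seen and holds AT5G22530, named above, so its test is not independent support. The 35 loci had a median of 0.59, with 32 above 0 (camera adjusted p = 1.2e-05, but adjusted p = 0.53 with an estimated correlation). In the blocked fit 5 of them rose, including AT5G22530 (1.95), AT1G65500 (1.75), AT5G18470 (1.61) and AT1G51890 (1.03, adjusted p = 0.043), and adjusted over the list alone 12 were higher and 1 lower. Without the block these counts were 0 over all genes tested, and 2 higher and 0 lower over the list alone. The list median was 0.63 in replicate 1 and 0.29 in replicate 2, and it was 0.31 without wild type replicate 1 and 0.39 without double KO-nudx6/7 replicate 2. AT5G18470 stood at 1.07 without double KO-nudx6/7 replicate 1 (adjusted p = 0.075). The 16 jasmonate and wound genes had a median of 0.38 and passed with the block (adjusted p = 0.047, but adjusted p = 0.42 with an estimated correlation) and not without it (adjusted p = 0.17). Without the block they passed when wild type replicate 2 (adjusted p = 0.045), KO-nudx6 replicate 1 (0.0074), KO-nudx7 replicate 1 (0.017) or double KO-nudx6/7 replicate 1 (0.003, median 0.72) was left out. Without double KO-nudx6/7 replicate 2 their median was 0.08 (adjusted p = 0.61), and the medians were 0.09 in replicate 1 and 0.73 in replicate 2. JAL23, PDF1.2 and PDF1.2b were their 3 members past the threshold in the blocked fit. These 3 are also among the named genes above, so the test of the jasmonate and wound list is not independent support either. The 8 loci of TIR-domain proteins had a median of 0.51 (blocked adjusted p = 0.047 and 0.17 without the block, adjusted p = 0.63 with an estimated correlation), and 0 of them passed singly in limma over all genes tested. Without the block that list passed in 1 of 8 leave-one-out fits, without wild type replicate 2 (adjusted p = 0.019, median 0.84). Its median was 0.00 without wild type replicate 1 (0.75) and 0.19 without double KO-nudx6/7 replicate 2 (0.59). The medians were 0.57 in replicate 1 and 0.17 in replicate 2. Of the ATG8 genes 9 of 10 lay above 0, with a median of 0.25 (adjusted p = 0.046 without the block and 0.062 with it, adjusted p = 0.53 with an estimated correlation). This call was lost with 75th percentile scaling (0.055), with the 4 arrays of these genotypes alone (0.059) and when wild type replicate 1 (0.42), KO-nudx6 replicate 1 (0.054), KO-nudx6 replicate 2 (0.064), KO-nudx7 replicate 2 (0.057) or double KO-nudx6/7 replicate 2 (0.23) was left out. The median was 0.12 without wild type replicate 1, 0.14 without double KO-nudx6/7 replicate 2 and 0.37 without wild type replicate 2. Of the 8 leave-one-out blocked fits, AT5G22530 and PDF1.2b passed in 4, AT1G65500 and AT5G18470 in 3 and AT1G51890 in 1.

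**Figure D4:**
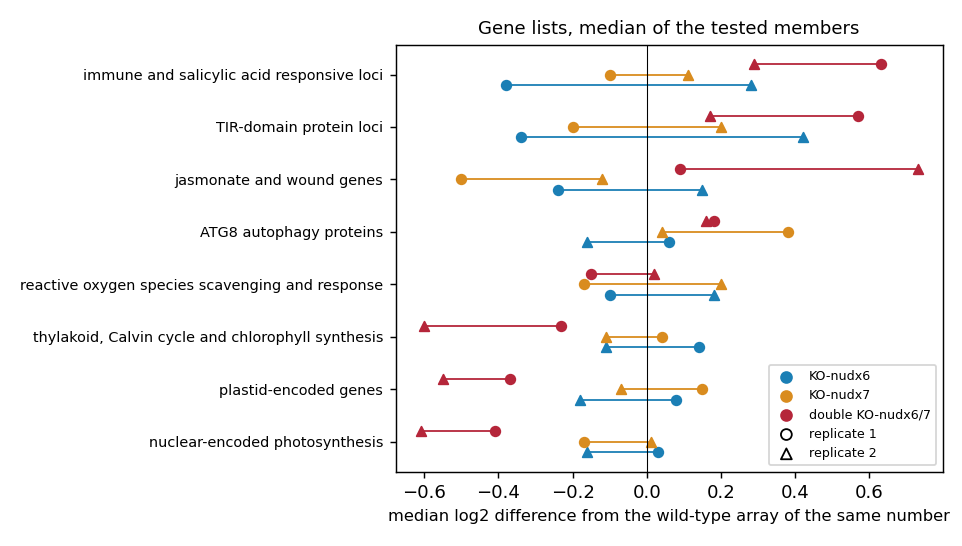
Median log2 difference from wild type of the same replicate number for the gene lists, by mutant, with a circle for replicate 1, a triangle for replicate 2 and a line joining them. In the double mutant the nuclear photosynthesis list lies at -0.41 and -0.61, and the immune list at 0.63 and 0.29.

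Members of other lists passed singly in the blocked fit of the double mutant against wild type. The thylakoid ascorbate peroxidase gene TAPX fell by 1.02 (adjusted p = 0.029), while its list of 5 reactive oxygen species genes had a median of -0.34 (adjusted p = 0.99). Its other members were AT2G21640 at 0.62, SAPX at -0.35, STZ at -0.34 and GR1 at 0.33. TAPX was also the 1 member past the threshold adjusted over the list alone in the blocked fit. The median of that list had no stable sign: it was -0.15 in replicate 1 and 0.02 in replicate 2, 0.15 without wild type replicate 2 and 0.40 without double KO-nudx6/7 replicate 1, and -0.73 without wild type replicate 1. Of 4 cold and abscisic acid response genes the dehydrin gene LTI30 fell by 1.36 (adjusted p = 0.037), and COR15A (-1.76, SE 0.45), COR15B (-0.92, SE 0.52) and COR47 (-0.71, SE 0.20) did not pass, with COR15A at a blocked adjusted p of 0.052. Adjusted over the list alone, all 4 of these cold genes passed in the blocked fit and 3, without COR15B, in the fit without it. The wider list of 16 cold, dehydration and osmotic stress genes, compiled later and holding these 4, did not pass, with a median of -0.03 and 8 of 16 above 0 (adjusted p = 0.53). In the blocked fit 1 of its members was higher, OSM34, and 1 lower, LTI30, which was at -0.88 without wild type replicate 2 (adjusted p = 0.32). AT2G04400 of the tryptophan pathway list rose by 1.0 (adjusted p = 0.026). The auxin-conjugating enzyme gene GH3.3 rose by 1.90 (adjusted p = 0.024), CML41 by 1.34 (adjusted p = 0.041) and UGT85A2 by 0.92 (adjusted p = 0.042). The auxin list of GH3.3 and the calmodulin-like list of CML41 had medians of -0.19 and -0.38 but means of 0.02 and 0.03, and did not pass (adjusted p = 0.81 and 0.91). Without wild type replicate 2 these medians were 0.14 and 0.47. In replicate 1 and 2 they were -0.16 and -0.05 for the auxin list and 0.25 and -0.58 for the calmodulin-like list, so neither gives a direction. Of the 8 leave-one-out blocked fits, GH3.3 passed in 4, TAPX in 3, AT2G04400, LTI30 and CML41 in 2 and UGT85A2 in 1.

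The other fixed lists had no member past the threshold over all genes tested in the double mutant against wild type, and of their members GSTU20 alone passed adjusted over the list alone, in the blocked fit (adjusted p = 0.0032 for a list of 1). Over the fixed lists together 6 of 45 members passed over all genes tested and 12 adjusted over the list alone with the block, against 0 and 6 without it. In salicylic acid signalling WRKY53 stood at 1.06 (SE 1.47), GRX480 at 0.52 (SE 0.60), SAG101 at 0.32 (SE 0.32) and AT5G52810 at 0.21 (SE 0.30). The 4 genes of protein folding in the endoplasmic reticulum lay between 0.27 (BZIP60, SE 0.33) and 0.45 (AT5G07340, SE 0.21), and GSTU20 at -0.69 (SE 0.36). Senescence genes were WRKY6 at 0.54 (SE 0.41), SAG29 at 0.39 (SE 0.99) and AT2G25625 at 0.32 (SE 0.63), glucosinolate genes BCAT4 at -0.54 and AT2G31790 at -0.36, and flavonoid genes DFR at -0.55 and UGT78D2 at -0.20. NAD metabolism genes lay near 0, with QPT at 0.18 (SE 0.17), NMNAT at 0.01 (SE 0.21) and AT1G55090 at -0.01 (SE 0.23). The receptor genes EFR (0.13) and BIK1 (0.01), the clock gene GI (0.03), the dividing-cell gene AUR1 (0.10), the root marker PYK10 (0.22) and the reference genes AT4G34270 (0.12), PEX4 (0.00) and AT2G28390 (0.00) did not pass. The heat shock, other Nudix and seed storage lists had 0 tested members.

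Compared with KO-nudx7 and with KO-nudx6, through the same double-mutant arrays, the double mutant again had higher OSM34 (3.13 and 2.89 on the log2 scale in the blocked fit), JAL23 (3.1 and 2.57), AT4G16260 (3.08 and 2.82), Prx37 (2.98 and 2.61) and PRX52 (2.79 and 2.78). It had lower AT2G47880 (-2.49 and -2.29), AT3G46490 (-2.09 and -2.38) and AT2G39850 (-1.77 and -2.28). AT4G10910 (-2.22) and AT3G14760 (-1.61) were further genes that fell against KO-nudx7, and AT3G62950 (-2.45), of the glutaredoxin family, and AT3G55710 (-1.81) against KO-nudx6. Mean signals lay below 89.0 in the double mutant for AT3G46490, AT4G10910, AT3G62950 and AT3G55710 and in KO-nudx7 for JAL23. These sizes are uncertain as well. The blocked fit called 545 probe sets against KO-nudx7 (296 higher, 249 lower) and 528 against KO-nudx6 (285 higher, 243 lower). Of the 168 and 179 probe sets called higher and lower against wild type, 126 and 104 were called in the same direction in all 3 comparisons. These comparisons share the double-mutant arrays, so part of this overlap may come from them. In 100 simulations of unchanged groups with the same sharing 0.01 higher and 0 lower calls were common to all 3 on average, and independent lists would share 0.076 and 0.058. The simulated groups gave 0.67 calls on average in the double mutant against wild type, so little could be shared. Neither value tells how much of the overlap comes from the shared double-mutant arrays. Without the block limma called 0 in each, with 1369 and 1376 at an unadjusted p under 0.05, against 3066 and 2961 in the blocked fit and 682 by chance. The smallest p without the block then belonged to AT3G46490, AT1G76470 (2.73, adjusted p = 0.18), AT5G44390 (1.51, from a mean signal of 57 in KO-nudx7), CYTC6A (-1.45) and AT2G04570 (-1.17) against KO-nudx7, and to AT3G46490, AT3G28540 (1.45), BGLU33 (-1.74), AT2G39850 and PRA1.F1 against KO-nudx6.

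The blocked counts of these comparisons moved with single arrays too. Against KO-nudx7 the count of 545 became 233 and 237 without KO-nudx6 replicate 1 and 2, 0 without either KO-nudx7 array (limma), 1220 without double KO-nudx6/7 replicate 1 and 149 without double KO-nudx6/7 replicate 2. Against KO-nudx6 the count of 528 became 9 and 35 without KO-nudx6 replicate 1 and 2, 25 without either KO-nudx7 array, 1245 without double KO-nudx6/7 replicate 1 and 221 without double KO-nudx6/7 replicate 2. The photosynthesis list was lower by a median of -0.40 against KO-nudx7 (adjusted p = 1.9e-04, but adjusted p = 0.26 with an estimated correlation) and -0.47 against KO-nudx6 (adjusted p = 4.5e-04, but adjusted p = 0.30 with an estimated correlation). Without double KO-nudx6/7 replicate 2 these medians were -0.21 and -0.22, and without KO-nudx6 replicate 1 the second was -0.20. The medians in replicate 1 and 2 were -0.21 and -0.58 against KO-nudx7, and -0.45 and -0.51 against KO-nudx6. Among the fixed lists PSAN, LHCB4.2, TAPX, LTI30, PDF1.2 and AT2G04400 passed against both single mutants in the blocked fit, as 6 of 45 against KO-nudx7 and, with GSTU20, 7 of 45 against KO-nudx6. Adjusted over the list alone the blocked counts were 17 and 15, and over all genes tested limma called 0 of them without the block in either comparison (6 and 9 adjusted over the list alone). The plastid-encoded genes were lower by medians of -0.49 (adjusted p = 8.9e-17, but adjusted p = 0.33 with an estimated correlation) and -0.36 (adjusted p = 1e-10, but adjusted p = 0.51 with an estimated correlation), and the second of these was -0.23 without KO-nudx6 replicate 1. The jasmonate and wound genes had a median of 0.59 against KO-nudx7 (adjusted p = 0.037, and 0.0043 with the block, but adjusted p = 0.71 with an estimated correlation), with 0.26 in replicate 1 and 0.67 in replicate 2. That median was 0.41 without KO-nudx7 replicate 1 (adjusted p = 0.078), 0.22 without double KO-nudx6/7 replicate 2 (0.67), 0.96 without KO-nudx7 replicate 2 (0.0021) and 0.91 without double KO-nudx6/7 replicate 1 (0.00056). Against KO-nudx6 it was 0.44, which passed with the block (adjusted p = 0.035, but adjusted p = 0.40 with an estimated correlation) and not without it (adjusted p = 0.14). Without the block that list passed against KO-nudx6 when KO-nudx6 replicate 2 (0.013), KO-nudx7 replicate 1 (0.010) or double KO-nudx6/7 replicate 1 (0.0044, median 0.78) was left out. Its median was 0.17 without double KO-nudx6/7 replicate 2 (0.75) and 0.27 without KO-nudx6 replicate 1 (0.25). The medians against KO-nudx6 were 0.28 in replicate 1 and 0.79 in replicate 2.

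Between KO-nudx7 and KO-nudx6 limma called 0 named genes and 0 probe sets without the block, with 111 at an unadjusted p under 0.05 against 682 by chance. The 5 named genes with the smallest p were CYP71B24 (0.68), AT2G40260 (0.83), AT5G27650 (-0.78), AT2G39500 (1.22) and AT2G12400 (-0.72), each with an adjusted p of 1. Of the fixed lists DFR (-0.97) passed adjusted over the list alone (adjusted p = 0.032 over 2 genes) and not over all genes tested. The blocked fit, with 361 at an unadjusted p under 0.05, called 263852_at (1.95, adjusted p = 0.039) and 254784_at (-4.07, adjusted p = 0.007), and without KO-nudx6 replicate 1 or KO-nudx6 replicate 2 the fit without the block called 1. The ATG8 genes had a median of 0.27 (adjusted p = 1.3e-05, but adjusted p = 0.65 with an estimated correlation), with medians of 0.36 and 0.11 in the replicate numbers, and 0.17 without KO-nudx7 replicate 1 (adjusted p = 0.082). The plastid-encoded genes had a median of 0.10 (adjusted p = 0.0024, but adjusted p = 0.72 with an estimated correlation), which was -0.07 without KO-nudx6 replicate 2 (adjusted p = 1) and -0.03 without KO-nudx7 replicate 1 (adjusted p = 0.74), but 0.26 without KO-nudx6 replicate 1 (adjusted p = 4.1e-05) and 0.25 without KO-nudx7 replicate 2 (adjusted p = 3.5e-06). The adjusted p was 0.082 with the stricter filter and 0.086 after quantile normalization.

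The interaction asks whether the double mutant departs from the sum of the single mutants' differences. AT1G26920 had an interaction of -5.10 on the log2 scale (SE 0.30, adjusted p = 0.0047), with differences from wild type of 4.32 in KO-nudx6, 4.6 in KO-nudx7 and 3.82 in the double mutant. It was the 1 call without the block, with 762 at an unadjusted p under 0.05 against 682 by chance, and the count was 0 without wild type replicate 1 (adjusted p of AT1G26920 0.062) or without KO-nudx7 replicate 1 (0.059). The blocked fit, with 2104 at an unadjusted p under 0.05, called 4 probe sets, 2 positive and 2 negative, the others being 266142_at (5.29), 265058_s_at (3.37) and 258239_at (-2.36), which are named by ID because the annotation lists no single gene for them. The photosynthesis list had a median interaction of -0.34 (adjusted p = 0.0093, but adjusted p = 0.48 with an estimated correlation), with medians of -0.27 without wild type replicate 2 (adjusted p = 0.091), -0.17 without KO-nudx6 replicate 1 (0.25), -0.14 without double KO-nudx6/7 replicate 2 (0.13) and -0.51 without KO-nudx6 replicate 2. Its medians were -0.24 and -0.47 in replicate 1 and 2. The plastid-encoded genes had a median interaction of -0.45 (adjusted p = 2.1e-10, but adjusted p = 0.55 with an estimated correlation) and medians of -0.73 and -0.22. The immune loci had a median of 0.63 (adjusted p = 2e-04, but adjusted p = 0.55 with an estimated correlation) and medians of 1.34 and 0.11, while the median became 0.45 without wild type replicate 2 (adjusted p = 0.053), 0.15 without KO-nudx6 replicate 1 (0.68) and 0.22 without KO-nudx7 replicate 1 (0.11), but 1.29 without KO-nudx6 replicate 2 and 1.08 without KO-nudx7 replicate 2. The jasmonate and wound genes had a median interaction of 0.57, which passed with the block (adjusted p = 0.0066, but adjusted p = 0.46 with an estimated correlation) and not without it (adjusted p = 0.064). Without the block its median was 0.21 without double KO-nudx6/7 replicate 2 (adjusted p = 0.64) and 1.03 without double KO-nudx6/7 replicate 1 (0.0012), and it passed in 4 of 8 leave-one-out fits. Of the fixed lists 2 members passed adjusted over the list alone without the block, AT2G04400 (1.17) and DFR (1.39), 7 with the block, and limma called 0 over all genes tested in both fits.

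The differences of the mutants from wild type share the wild-type arrays, so part of any likeness between them comes from these arrays. In the blocked fit KO-nudx6 and KO-nudx7 shared 1 call, the higher AT1G26920, and each shared 2 with the double mutant, AT1G26920 and 1 lower probe set. Simulated unchanged groups with the same wild-type arrays shared on average 0.09, 0.10 and 0.08 calls, and independent lists would share 7.3e-05 higher calls between the single mutants and 0.012 between either and the double mutant. The simulated groups had only 0.59 to 0.74 calls per comparison on average. These values therefore do not show how much of the sharing of calls comes from the wild-type arrays. Across probe sets the differences of KO-nudx6 and KO-nudx7 correlated at 0.54, where 100 simulations of unchanged groups with shared wild-type arrays gave 0.50 (0.48 to 0.52), with a covariance of 0.0264 against 0.0228 simulated. KO-nudx6 and the double mutant correlated at 0.15 and KO-nudx7 and the double mutant at 0.18, with covariances lower than the simulated one by -0.0094 and -0.005. With 2 wild-type arrays no split into sets of at least 2 was possible, and part of the correlations may come from the shared arrays.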

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

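The same-number test of AT1G26920, the same-sign and 3'/5' ratio tests of the double mutant, and the random lists within replicate numbers and without single arrays were chosen after the result was seen. The interaction of AT1G26920 was -5.10 (adjusted p = 0.0047, and 0.00027 in the blocked fit), from signals of 40 and 51 in wild type, 1100 and 911 in KO-nudx6, 1328 and 1106 in KO-nudx7, and 786 and 634 in the double mutant. In the blocked fit the interaction of 266142_at was 5.29 (adjusted p = 0.004), with 3842 and 8242 in the double mutant and 174 to 603 on the other 6 arrays. The interaction of 265058_s_at was 3.37 (adjusted p = 0.01), with 2315 and 4559 in the double mutant against 847 and 1274 in wild type. The interaction of 258239_at was -2.36 (adjusted p = 0.004), with 1333 and 895 in the double mutant against 6970 and 5750 in wild type. The last 3 had adjusted p of 0.63, 0.86 and 0.63 without the block.

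AT1G26920 was far lower in wild type than in all 3 mutant genotypes, which share no single knockout. The difference between replicate numbers is argued against by the lowest of the 6 differences from the wild-type array of the same number, 3.51 on the log2 scale. A chromosome segment with most genes altered is argued against by the 20 nearest tested genes, whose mean size of effect lay at percentile 37.5 of all such runs. A segment with a few altered genes stays open, as a mean over 20 genes can miss them. Probe sets with no listed gene had no position and did not enter this test. Wild-type arrays that stand apart in general are argued against by the blocked comparison of wild type with the mean of the mutants, which called 1 probe set. A candidate explanation left open is a response common to both losses, or a difference in the wild-type seed stock at or near this gene, which these data did not test.

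The double mutant differed from wild type at more probe sets than either single mutant in the blocked fit. Of the 100 largest differences of replicate 1, 84 had the same sign in replicate 2, so most of these were shared by both numbers. The same count was 75 in KO-nudx7, where the blocked fit called 2, so it does not account for the number of calls. Differences of at least 2-fold numbered 371 in replicate 1 and 1015 in replicate 2. A larger deviation of 1 double-mutant array therefore stays open. The scaling of the arrays is argued against by the 377 probe sets called after quantile normalization. Degraded RNA in the double mutant stays open: its mean 3'/5' ratio differed from that of the other genotypes by 0.04 in replicate 1 and -0.24 in replicate 2 on the log2 scale, and a single lower array excludes nothing. An effect of losing both genes stays open beside these, and rests on the blocked fit and on few arrays.

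Transcripts of the 7 tested nuclear photosynthesis genes and plastid-encoded transcripts were lower in the double mutant. Compressed bright signals are argued against for the plastid list, whose median of -0.45 lay below the 2.5th percentile of 10000 random lists of matched signal (-0.12), as it did in both replicate numbers and without each wild-type or double-mutant array. They stay open for the photosynthesis list, whose median of -0.55 lay below that percentile (-0.48) with all arrays, but at percentile 3 of such lists in replicate 2 and 3.3 without double KO-nudx6/7 replicate 2. The random lists matched to the photosynthesis list had a median of -0.24 themselves, so part of its -0.55 was shared by probe sets of similar signal. Dilution by the transcripts that rose would need 31.8% of the total signal, and the probe sets called higher gained 1.44%. A lower level of photosynthetic transcripts in the double mutant and a difference in RNA quality both stay open, and both list calls were lost with an estimated correlation.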

How the results depend on the processing

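The alternatives of the blocked fit and the lists compiled from the annotation were chosen after the result was seen. The blocked fit changed the count from 1 to 2 in KO-nudx6 and KO-nudx7, from 2 to 347 in the double mutant against wild type, from 0 to 2 for KO-nudx7 against KO-nudx6, to 545 and 528 for the double mutant against KO-nudx7 and KO-nudx6, and from 1 to 4 for the interaction. It moved 81 of 368 named-gene results past the threshold, but the rule had also named genes because they passed in the blocked fit. With 1 array per genotype in each number, the block leaves the log2 differences themselves unchanged, so no sign could reverse. The blocked fit changed 5 of 91 tests of added lists and 0 of 14 tests of fixed lists. Members of the fixed lists that passed adjusted over the list alone went from 6 to 12 in the double mutant against wild type. With only the 4 arrays of the groups compared the counts were 0 in KO-nudx6 and 2 in KO-nudx7. No filter and the 60th percentile filter each left 1 in the double mutant against wild type, and quantile normalization, 75th percentile scaling and eBayes without a trend each gave 1 for the double mutant against KO-nudx7. Leaving out each array gave 1 to 2 in KO-nudx7, 0 to 2 in the double mutant, 0 to 1 for KO-nudx7 against KO-nudx6, for the double mutant against either single mutant, and for the interaction. With an estimated correlation the photosynthesis list had adjusted p of 0.20, or 0.11 with the block, against wild type, and 4 of the 14 tests of fixed lists were lost. The same list in KO-nudx6 ranged from 0.0095 to 0.85 over the left-out arrays. The plastid list of KO-nudx7 against KO-nudx6 ranged from 3.5e-06 to 1 over the left-out arrays, with a reversed direction at 0.74 and 1. With the block kept, the counts of the double mutant against wild type, KO-nudx7 and KO-nudx6 were 101, 196 and 182 without the filter, 203, 322 and 303 without a trend, and 211, 297 and 310 with a 2-fold limit, and they were within 1.5 times of the blocked counts under the other settings that kept all arrays. Scaling to the 75th percentile called 244 higher and 321 lower against KO-nudx7, where the blocked fit called 296 and 249. Leaving out each array gave 2 to 972, 0 to 1220 and 9 to 1245. No named gene of the blocked fit reversed; of 86 such results, 25 were lost without the filter and 74 without either KO-nudx7 array. The cause was not tested, except that fewer arrays were fitted where arrays were left out. In the fit without the block, leaving out an array of a compared genotype also set unequal replicate numbers against each other. Signal over background was not analysed here, so dim probe sets are limited by the filter alone.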

Other observations

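The values in this part were chosen after the result was seen. A few probe sets for which the annotation lists no gene had large differences in the double mutant against wild type in the blocked fit, and they were chosen after their values were seen. They were 266142_at at 3.53, 252265_at at 3.42 and 254820_s_at at -3.07 on the log2 scale. The probe set 254784_at, whose signals are given above, was also lower, with values between -3.74 and -3.15 when single arrays were left out. In the leave-one-out blocked fits 266142_at passed in 7 of 8, with values between 3.1 and 3.95, 252265_at in 5 and 254820_s_at in 4. The mean signal of 254820_s_at in the double mutant was 48, below the 89.0 of the filter on dim probe sets, so the size of its difference is uncertain.

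Differences of at least 2-fold with the same sign in both replicate numbers were found at 161 probe sets in the double mutant against wild type, where 13.8 would be expected if the numbers were independent. The same counts were 5 in KO-nudx6, with 0.5 expected, and 12 in KO-nudx7, with 0.4 expected. These values have no test.

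The immune and salicylic acid responsive loci had medians of opposite sign on the KO-nudx6 arrays, a difference that was not tested. Their median against the wild-type array of the same number was -0.38 in replicate 1 and 0.28 in replicate 2, and the list did not pass in KO-nudx6 against wild type with all arrays (median -0.07, adjusted p = 0.49, and 0.37 with the block). Both the call and its sign turned on single arrays in the fit without the block: the median was -0.64 without KO-nudx6 replicate 2 (adjusted p = 2.3e-13), -0.36 without wild type replicate 1 (0.017), 0.57 without KO-nudx6 replicate 1 (4.8e-06) and 0.30 without wild type replicate 2 (0.66). Each of these sets arrays of unequal replicate numbers against each other, so none of them gives the list a direction.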
